A study of Mus musculus with 12 samples.

How the data were processed

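The data are 12 single-color Affymetrix expression arrays of mouse cells, with biotin-labelled total RNA prepared by the standard protocol of the manufacturer, per the labels. The design text describes mice with or without the genes Stat5a and Stat5b in blood cells, and each label states a control or a knockout and a treatment field that says with or without "GMP". Titles of some untreated arrays carry the same letters, so it is unclear whether they name an agent or the cells, and only the word treatment is used here. The 4 groups are control untreated, control treated, knockout untreated and knockout treated, with 3 arrays each. The sample titles place the arrays on 3 dates, and each date holds 1 array of every group. On date 2 the title of the knockout treated array carries another number tag than the titles of the other 3 arrays of that date. No label says what this tag marks. No label says that the samples came from separate animals, so p-values measure only the spread between these samples, part of which may be technical. Signals of Xist and the Y-linked Eif2s3y show that the mice of date 1 were not those of the other dates, in each group, and the number of mice per sample is not known.

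The authors deposited an intensity on a linear scale for each of 45101 probe sets, made with MAS5, per the submitters' processing notes. No version, scaling target or masking is given in the sources used here. In the deposited intensity values the mean of each array after trimming 2% at either end lies between 500.003 and 500.004, so the arrays had been scaled to a common mean. A broad rise among probe sets inside the trimmed range lowers the others on such a scale. MAS5 subtracts mismatch signal, which makes dim values unstable. The number of arrays limits the precision, and no count depth exists for an array. All 12 columns of the deposited table belong to the 12 samples, and no column was left out.

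Probe sets were named through the platform annotation. Of the probe sets, 34945 carried 1 gene symbol, 932 carried several, 9160 carried none and 64 were control probe sets, and only those with 1 symbol were used. For 34754 of the 34945 the gene identifier was found in a current RefSeq gene table, and 0 symbols changed. A probe set was tested if its intensity exceeded 70.5495, the median of all values, on at least 3 of the 12 arrays, which left 21363 probe sets. Where several probe sets of a gene passed, the 1 with the highest mean of the log2 values over the 12 arrays stood for the gene, with sets marked as cross-hybridizing used only if no other was left. This gave 11815 genes, of which 5484 had more than 1 passing probe set. Among 142 other passing probe sets of the named genes that passed the test, 2 had the opposite direction. Socs2 is a gene for which this rule chose a probe set that differed from 2 others, and its other probe sets are given with it. No genome was used, and no coordinates are given.

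Values were taken as log2 of the intensity plus 13, the 20th percentile of all values rounded to a whole number, so a fold change of a dim gene is understated. limma 3.58.1 in R 4.3.3 fitted the 4 groups with array date as a block, moderated the variances (6 residual and 3.96 prior degrees of freedom), and gave log2 changes with standard errors for 5 comparisons. These were treatment in control cells, treatment in knockout cells, the difference between the 2 responses, and knockout against control without and with treatment. p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. All 12 arrays entered each fit, so that the 4 groups shared the estimate of the spread. A 95% confidence interval reached a median of 0.644 to either side of the estimate on the log2 scale, and 0.911 for the difference of responses. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

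The block was part of the planned fit because the titles give the dates. The pairing was checked on the deviations of arrays from their group means across genes. For the 18 pairs of arrays of the same date the correlation lay between 0.357 and 0.753, and for 36 pairs of different dates between -0.661 and 0.399. Without the block 82 of 178 called values of named genes lost their call, and these are counted under each comparison.

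In all, 26 gene lists were written down in advance: STAT5 and cytokine feedback targets, anti-apoptotic and pro-apoptotic genes, cytokine and growth factor receptors, primary granule genes, secondary and tertiary granule genes, monocyte and macrophage genes, dendritic cell and MHC class II genes, myeloid transcription factors, stem and early progenitor genes, cell cycle genes, ribosome biogenesis and MYC-linked growth genes, cholesterol synthesis genes, glycolysis genes, oxidative phosphorylation genes, amino acid response and starvation genes, chemokines and inflammatory cytokines, interferon response genes, immediate early and heat shock genes, and markers of erythroid, megakaryocyte and platelet, mast cell and basophil, eosinophil, B lineage, T and NK lineage, stroma and endothelium, and sex-linked expression. The lists share some genes. Each was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, and again with a correlation estimated from the arrays. p-values were adjusted over the 130 list tests. With the preset correlation 41 of the 130 were called, with an estimated correlation 0, and without the block 41. Without date 2 an estimated correlation called 0 as well. fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, called 22. Counts of list members are given over all genes tested and adjusted over the list alone.

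The rule for the genes to name took, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with the same sign on all 3 dates and a higher group mean of at least 4 times the added constant. Symbols of uncharacterized genes were counted and not named by it. Where no gene passed, it took the 5 in each direction with the smallest p. Stat5a, Stat5b, Cish, Socs2, Pim1, Mpo, Elane, Ltf, Camp and Csf1r were always named, as were up to 4 members of each list with the smallest p. The design, this rule, the lists and the alternatives were chosen before the data were examined, except array weights and list tests without date 2 (with the preset or an estimated correlation), which were added after seeing the data. For 10 genes lower in treated knockout cells, array date 2 was first tested by calls from dates 1 and 3 alone, with 0 called. A criterion on the size of the difference was set later, with the estimates in view. The forms considered were a margin of 1 SE, a margin of 2 SE, and the median ratio less its SD over genes (0.938 and 0.0925). Each gave the same answer, which picking the genes on all dates favored. The alternatives were no block, date as a random block, other added constants, no filter and a stricter one at 417.649, quantile normalization, equal medians, other uses of the probe sets, only the 2 groups compared, an intensity trend, a fold threshold, leaving out each date, and leaving out each array.

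The fit was tested on simulated data built from these arrays with 100 genes changed at each size. In the control treatment comparison it recovered 24% of genes changed by 1 on the log2 scale and 91% of those changed by 2. In the difference of responses it recovered 0% and 55%. The simulated noise of a gene was independent and equally large on all arrays. Array weights estimated from the data were 0.215 to 0.649 on date 2 and 0.748 to 2.80 on the other dates. These rates may therefore not hold for the real arrays. Lists of unchanged genes, simulated as independent, had p under 0.05 in 4.42% of tests over 20 simulated sets.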

Results

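Messenger RNA was measured in cells of mice that carried or lacked Stat5a and Stat5b in blood cells. These genes encode the paired STAT5 transcription factors that act downstream of GM-CSF and related cytokine receptors. Which cells were assayed is not clear from the labels. Cells of either genotype were untreated or treated, which gave 4 groups of 3 arrays. The arrays were run on 3 dates with 1 array of each group per date. Each array reported 45101 probe sets scaled to a trimmed mean near 500, and 11815 genes were tested. The question posed by the series is how far STAT5 governs the granulocyte-forming response to GM-CSF.

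The arrays of date 2 stood apart from the others. The signal of a probe set at the 3' end over that at the 5' end of the same transcript, which rises when RNA or its labelled copies are short, was 20.8 to 266 for Actb and 28.2 to 80.7 for Gapdh on date 2. On the other dates it was 1.14 to 2.05 for Actb and 1.56 to 3.90 for Gapdh. On date 2 the ratio for Actb was 59.5 in control untreated, 266 in control treated, 28.7 in knockout untreated and 20.8 in knockout treated cells. The median rank correlation across probe sets of an array with the other 11 was 0.814 to 0.885 on date 2 and 0.911 to 0.922 on the other dates. The first principal component, with 41.0% of the variance, separated date 2, and the second, with 25.3%, separated treated from untreated arrays.

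**Figure D1:**
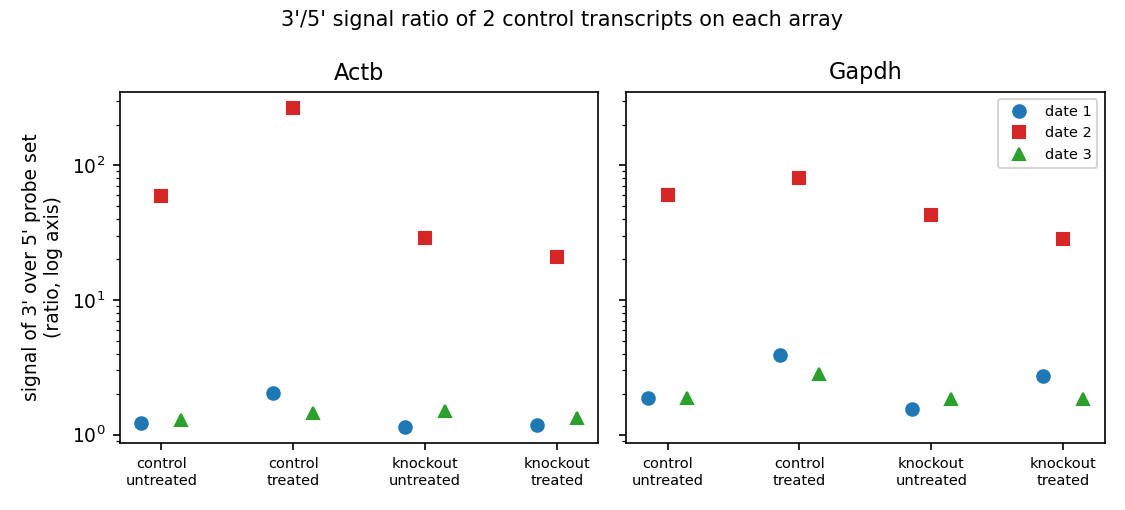
Ratio of the signal of the 3' probe set to that of the 5' probe set (log axis, no unit) for Actb and Gapdh on each of the 12 arrays, by group, with 1 symbol per array date. The 4 arrays of date 2 sit between 20.8 and 266 for Actb, and the other 8 between 1.14 and 2.05.

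Stat5a and Stat5b were low on all 6 arrays labelled knockout. The Stat5a signal was 962 ± 165 in control untreated, 653 ± 254 in control treated, 60.6 ± 35.4 in knockout untreated and 36.0 ± 8.84 in knockout treated cells (SD, n = 3 arrays each). The Stat5b signal was 1120 ± 535, 837 ± 481, 41.3 ± 15.0 and 30.2 ± 29.4 in the same order. The lowest control array lay at 375 for Stat5a and 287 for Stat5b, and the highest knockout array at 101 and 60.5. A dimmer probe set of Stat5b was lower in knockout cells by -1.55 ± 0.29 without and -2.06 ± 0.29 with treatment on the log2 scale. For a dimmer probe set of Stat5a these values were -0.80 ± 0.56 and -1.62 ± 0.56. Which part of each gene was deleted is not stated in the labels, so a probe set outside it would check nothing.

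**Figure D2:**
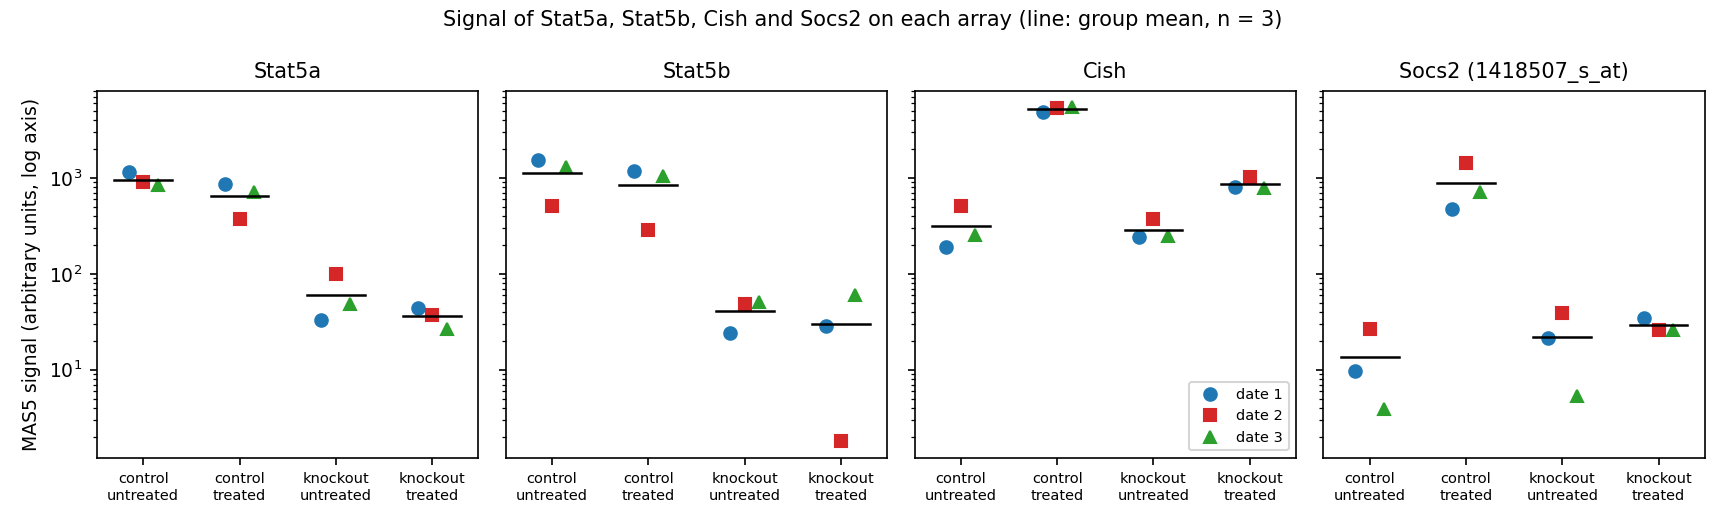
MAS5 signal (arbitrary units, log axis) of Stat5a, Stat5b, Cish and a Socs2 probe set on each array by group, with 1 symbol per array date and a line at the mean of 3 arrays. Stat5a and Stat5b are low in both knockout groups, and Cish reaches a mean of 5203 in control treated and 869 in knockout treated cells.

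Treatment of control cells was followed by rises of Acod1 and Emp1 from signals near the background. Acod1, which makes itaconate in activated macrophages, went from a signal of 7.47 ± 3.94 to 5377 ± 5410 (SD, n = 3), a log2 rise of 7.30 ± 0.68 (SE, limma, Benjamini-Hochberg adjusted p = 4.21e-04). The membrane protein gene Emp1, at 4.29 ± 2.98 before treatment, rose by 7.83 ± 0.66 (adjusted p = 2.58e-04), the lipoprotein lipase gene Lpl by 5.31 ± 0.44, the glycerol channel gene Aqp9 by 5.17 ± 0.39 and the stress regulator Nupr1 by 4.83 ± 0.34. Cish, a feedback inhibitor of cytokine receptors and a known STAT5 target, rose by 4.10 ± 0.26 (adjusted p = 1.12e-04), from 317 ± 172 to 5203 ± 314. Fosb fell by 5.30 ± 0.48, the heat shock genes Hspa1a and Hspa1b fell by 4.14 ± 0.31 and 3.93 ± 0.50, and Fos and Jun fell by 3.39 ± 0.44 and 2.76 ± 0.43. In all, 800 of 11815 genes changed at an adjusted p under 0.05 in limma, 497 upward and 303 downward, 672 of them by at least 1 on the log2 scale, and 798 had the same sign on all 3 dates. At an unadjusted p under 0.05 there were 2754.

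Other large rises were those of Ccl5 (5.33 ± 1.11), Serpinb2 (4.96 ± 1.05), Relb (4.88 ± 0.75), Bhlhe40 (4.79 ± 0.51) and Cxcl10 (4.71 ± 0.95). Other large falls were those of the histone genes H3f3b (-3.94 ± 0.55) and H3c4 (-3.01 ± 0.30), Phldb2 (-2.94 ± 0.35), Btnl9 (-2.86 ± 0.53) and the choline dehydrogenase gene Chdh (-2.79 ± 0.35). Before treatment Acod1, Emp1, Nupr1 and Relb had mean signals below the added constant of 13, so their rises are understated and have no order. Of 78 named genes past the threshold in control cells, 39 stayed past it in each of the 12 fits without 1 array. Among those named above, Ccl5, Serpinb2, Cxcl10 and Btnl9 did not, with adjusted p of at most 0.0924, 0.0983, 0.0739 and 0.0627. Ccl5 lost its call without control treated replicate 1 or 3 or control untreated replicate 1 or 2, Serpinb2 and Cxcl10 without control treated replicate 1 or 3 or control untreated replicate 1 or 3, and Btnl9 without control untreated replicate 1 or 2.

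Socs2, a second feedback inhibitor and STAT5 target, gave different values on its probe sets. The set that stood for the gene, with a signal of 102 ± 47.8 in control untreated and 149 ± 48.7 in control treated cells, differed by 0.55 ± 0.36 (adjusted p = 0.409). A probe set at 13.5 ± 11.9 before treatment reached 878 ± 506 after it, a log2 rise of 5.01 ± 0.36 with an adjusted p of 1.56e-04 over the 21363 probe sets tested separately in limma. Another went from 22.6 ± 29.6 to 638 ± 243 and rose by 4.44 ± 0.33 (adjusted p = 1.97e-04). These 2 Socs2 probe sets were singled out after their values were seen.

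The 26 STAT5 and cytokine feedback targets measured had a median log2 change of 0.77, with 6 genes up and 0 down over all genes tested and 12 up adjusted over the list alone. The list ranked above other genes (camera adjusted p = 1.81e-05; adjusted p = 0.185 with an estimated correlation). Beside Cish, the kinase gene Pim1 rose by 1.60 ± 0.24 (adjusted p = 0.00555), the cell cycle inhibitor gene Cdkn1a by 3.51 ± 0.32, the survival gene Bcl2l1 by 1.51 ± 0.24 and Spred1 by 2.04 ± 0.22. Of 31 amino acid response and starvation genes 11 rose, and 19 rose and 1 fell adjusted over the list alone (median 1.26, adjusted p = 1.49e-10; adjusted p = 0.192 with an estimated correlation). They included the glutathione-degrading enzyme gene Chac1 (4.48 ± 0.50), the cystine transporter gene Slc7a11 (4.34 ± 0.34) and Slc7a3 (3.80 ± 0.45). Of 33 chemokines and inflammatory cytokines 9 rose, 19 adjusted over the list alone (median 1.56, adjusted p = 7.03e-10; adjusted p = 0.457 with an estimated correlation). Tnf (3.46 ± 0.59) and Cxcl3 (3.78 ± 0.67, from a signal of 9.63 ± 5.95, below the added constant) were among them. The adjusted p was 0.0547 for Tnf without control treated replicate 3 and 0.0528 for Cxcl3 without control untreated replicate 2.

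Monocyte and macrophage genes had 12 members up and 3 down of 36 (median 0.98, adjusted p = 4.72e-05; adjusted p = 0.185 with an estimated correlation), and 18 up and 6 down adjusted over the list alone. The lectin receptor genes Clec4d and Clec4e rose by 3.80 ± 0.23 and 2.84 ± 0.37. The monocyte receptor gene Csf1r differed by 0.56 ± 0.22 (adjusted p = 0.155). Of 24 dendritic cell and MHC class II genes 7 rose, 9 up and 1 down adjusted over the list alone (median 0.24, adjusted p = 0.0313; adjusted p = 0.567 with an estimated correlation). These included the transcription factor gene Batf3 (4.55 ± 0.64), Cd83 (3.01 ± 0.47) and the costimulatory gene Cd86 (2.57 ± 0.31). Myeloid transcription factors had 9 up and 4 down of 44, and 19 up and 7 down adjusted over the list alone (median 0.51, adjusted p = 0.00565; adjusted p = 0.457 with an estimated correlation). Maf rose by 3.68 ± 0.50 and Nab2 by 3.31 ± 0.45. Cholesterol synthesis genes had 7 of 20 up and 9 adjusted over the list alone (median 0.80, adjusted p = 1.79e-04; adjusted p = 0.457 with an estimated correlation). Msmo1 rose by 2.57 ± 0.34, Cyp51 by 1.79 ± 0.28 and Insig1 by 1.66 ± 0.24.

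Among 84 cell cycle genes 6 fell and 0 rose, 18 fell adjusted over the list alone (median -0.47, adjusted p = 8.13e-08; adjusted p = 0.457 with an estimated correlation). The DNA ligase gene Lig1 changed by -0.94 ± 0.20 and the kinase gene Aurkb by -0.97 ± 0.22. The former lost its call without control treated replicate 1 or 3 or control untreated replicate 1 or 3 (adjusted p of at most 0.126). The latter lost it without each of the 6 control arrays in turn and without knockout treated replicate 3 (at most 0.136). Glycolysis genes had 4 down and 1 up of 20, and 8 down and 1 up adjusted over the list alone (median -0.55, adjusted p = 0.0274; 0.0568 without the date block; adjusted p = 0.539 with an estimated correlation). The phosphofructokinase gene Pfkl fell by 1.48 ± 0.27, with an adjusted p of at most 0.0623 without control untreated replicate 1 or 3. Of 51 oxidative phosphorylation genes 1 fell, also adjusted over the list alone (median -0.31, adjusted p = 0.00267; adjusted p = 0.759 with an estimated correlation). It was Cox7c (-1.87 ± 0.34), with an adjusted p of at most 0.0590 without control untreated replicate 2 or 3. Ribosome biogenesis and MYC-linked growth genes had 1 up and 3 down of 61, and 2 up and 5 down adjusted over the list alone (median -0.31, adjusted p = 0.00931; adjusted p = 0.593 with an estimated correlation). The member that rose was Mthfd2, a mitochondrial folate enzyme gene, by 2.44 ± 0.20. Of 27 immediate early and heat shock genes 7 fell and 1 rose, and 8 fell and 2 rose adjusted over the list alone (median -0.38, adjusted p = 0.00912; adjusted p = 0.544 with an estimated correlation; 0.0967 without date 2).

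Interferon response genes had 3 up and 1 down of 40, the same counts adjusted over the list alone (median 0.73, adjusted p = 0.010; adjusted p = 0.786 with an estimated correlation). Rsad2 changed by 3.07 ± 0.78 (adjusted p = 0.0445), with 5.78, 0.95 and 2.47 on the 3 dates. It stayed past the threshold in only 2 of the 12 fits without 1 array, those without control treated or knockout treated replicate 2 (at most 0.168 in the others). Anti-apoptotic and pro-apoptotic genes had 6 up and 1 down of 22, and 9 up and 2 down adjusted over the list alone (median 0.33, adjusted p = 0.00710; adjusted p = 0.457 with an estimated correlation). Birc3 rose by 1.40 ± 0.22 and Bcl2 fell by 1.10 ± 0.20, the latter with an adjusted p of at most 0.0705 without control treated replicate 3 or control untreated replicate 1. Cytokine and growth factor receptors had 5 up and 1 down of 25 and 7 up and 1 down adjusted over the list alone (median 0.30, adjusted p = 0.0867; 0.0462 without the date block; adjusted p = 0.539 with an estimated correlation). Csf2rb, which encodes the signalling chain of the GM-CSF receptor, and its neighbor Csf2rb2 for the IL-3 receptor rose by 1.66 ± 0.28 and 2.98 ± 0.40. Without control treated replicate 3 the adjusted p of Csf2rb was 0.0521.

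The granule genes were not called as lists in control cells. Primary granule genes had 0 of 20 past the threshold on either count (median -0.16, adjusted p = 0.225). Mpo, the myeloperoxidase gene, differed by 0.45 ± 0.25 (adjusted p = 0.317) and Elane, the neutrophil elastase gene, by -0.47 ± 0.32 (adjusted p = 0.434). Secondary and tertiary granule genes had 2 up and 1 down of 34, and 3 up and 2 down adjusted over the list alone (median -0.24, adjusted p = 0.463). Ltf differed by -0.56 ± 0.55 (adjusted p = 0.599) and Camp by -1.33 ± 0.49 (adjusted p = 0.136), and the arginase gene Arg2 rose by 2.90 ± 0.44. Stem and early progenitor genes had 1 up and 2 down of 35, and 1 up and 3 down adjusted over the list alone (median -0.01, adjusted p = 0.609). Markers of other cell types were not called as lists in this comparison. The adjusted p was 0.20 for erythroid markers (11 genes, median -0.20), 0.259 for megakaryocyte and platelet (16, 0.13), 0.663 for mast cell and basophil (8, -0.28), 0.385 for eosinophil (5, -0.44), 0.657 for B lineage (9, -0.30), 0.364 for T and NK lineage (8, 0.22), 0.867 for stroma and endothelium (11, median -0.13 and mean 0.05) and 0.687 for sex-linked genes (4, 0.30).

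The count of 800 depended on the block and on single arrays. Without the date block it was 165, and all 165 were among the 800, and with only the 2 groups fitted it was 214. Of the 78 named genes 44 stayed past the threshold without the block and 34 did not. Among those given above, these were Jun, Ccl5, Serpinb2, Tnf, Lig1, Aurkb, Pfkl, Rsad2 and Bcl2, at adjusted p of 0.0791 to 0.685. It was 322, 371 and 264 without control untreated replicate 1, 2 or 3, 366 and 237 without control treated replicate 1 or 3, 526 without knockout treated replicate 3 and 531 without knockout untreated replicate 3. Without date 2 it was 1146, of which 624 were shared with the 800.

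**Figure D3:**
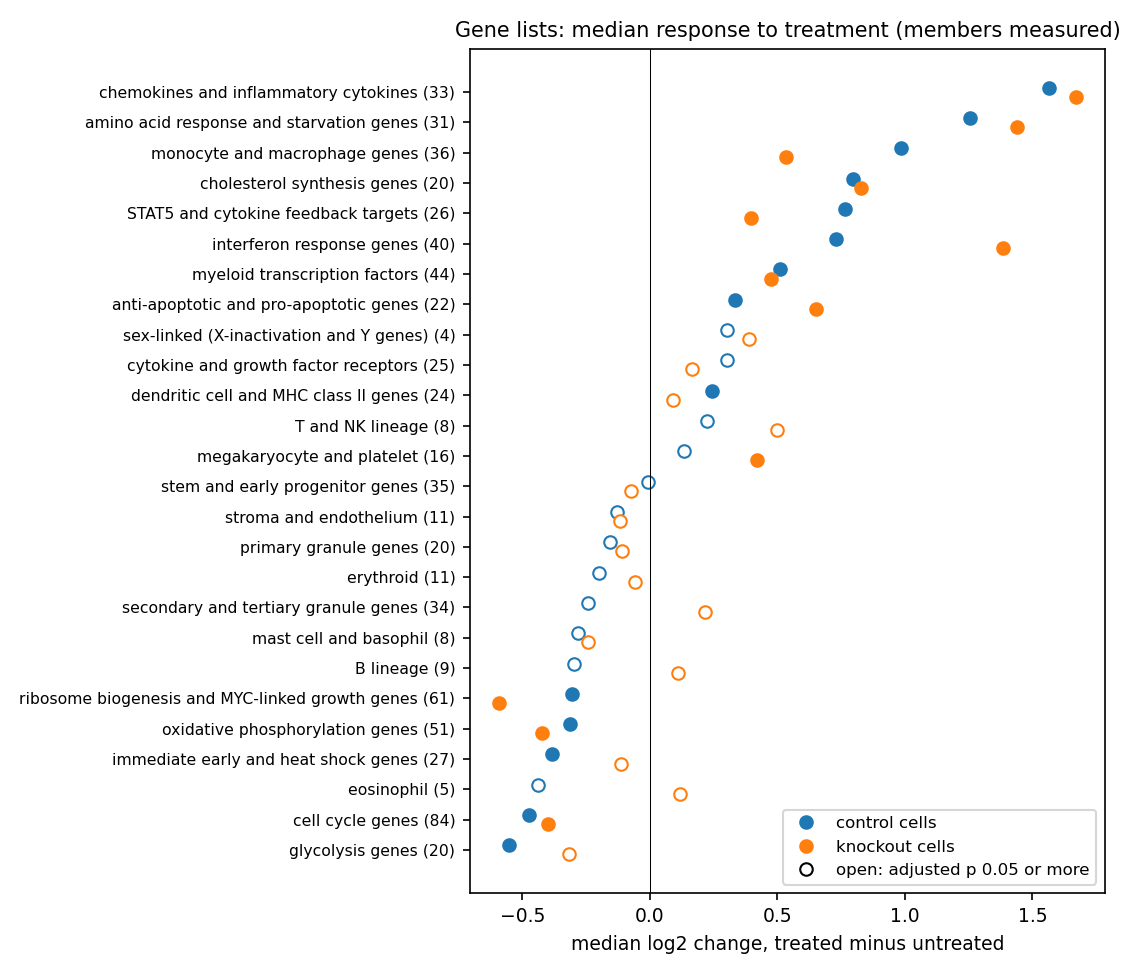
Median log2 change with treatment (treated minus untreated) of the measured members of each of the 26 gene lists, in control and knockout cells, with filled circles where the camera adjusted p was under 0.05. Chemokines and inflammatory cytokines lie highest, at 1.56 in control and 1.67 in knockout cells, and ribosome biogenesis genes at -0.31 and -0.59.

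Treatment of knockout cells was followed by rises of many of the same genes. Acod1 rose by 8.54 ± 0.68 (SE, limma adjusted p = 2.59e-04), from a signal of 5.87 ± 2.71 to 7573 ± 3800 (SD, n = 3), Emp1 by 6.58 ± 0.66, Lpl by 5.11 ± 0.44, Slc7a11 by 5.10 ± 0.34 and the chemokine gene Ccl5 by 7.21 ± 1.11. Cish rose by 1.58 ± 0.26 (adjusted p = 0.00551), from 287 ± 73.9 to 869 ± 128, and Pim1 by 1.68 ± 0.24 (adjusted p = 0.00301). The Socs2 probe set that rose by 5.01 in control cells differed by 0.39 ± 0.36 here (adjusted p = 0.558 over all probe sets), at 22 ± 16.9 before and 29.1 ± 5.08 after treatment, the other Socs2 probe set that had risen by 0.79 ± 0.33 (adjusted p = 0.176), and the set that stood for the gene by -0.14 ± 0.36 (adjusted p = 0.845). Fosb fell by 4.99 ± 0.48, Hspa1a by 4.02 ± 0.31, Hspa1b by 3.37 ± 0.50, and the cytokine receptor gene Il31ra by 4.31 ± 0.68. Of 11815 genes 1321 changed in limma, 795 upward and 526 downward, 1052 by at least 1 on the log2 scale and 1320 with the same sign on all 3 dates, and 3221 had an unadjusted p under 0.05.

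Other large rises in knockout cells were Cxcl10 (5.83 ± 0.95), Relb (5.78 ± 0.75), the acute phase gene Saa3 (5.45 ± 0.66), Rsad2 (5.10 ± 0.78) and Serpinb2 (5.05 ± 1.05), and other large falls were Tmem178 (-3.44 ± 0.64), Jun (-2.84 ± 0.43), Dio2 (-2.77 ± 0.42), Chdh (-2.72 ± 0.35), Map2k6 (-2.63 ± 0.44) and Chst13 (-2.59 ± 0.38). Acod1, Ccl5, Nupr1 and Serpinb2 before treatment and Il31ra after it had mean signals below 13 here, so these changes are understated. Serpinb2 lost its call without replicate 1 or 3 of knockout treated or knockout untreated cells (adjusted p of at most 0.0774). Of 88 named genes past the threshold in knockout cells, 59 stayed past it in each of the 12 fits without 1 array.

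Of 33 chemokines and inflammatory cytokines 14 rose, and 20 adjusted over the list alone (median 1.67, camera adjusted p = 1.49e-10; adjusted p = 0.457 with an estimated correlation). Tnf (4.44 ± 0.59) and Tnfsf9 (3.60 ± 0.36) were among them. Of 31 amino acid response genes 16 rose, and 19 adjusted over the list alone (median 1.44, adjusted p = 9.40e-10; adjusted p = 0.192 with an estimated correlation). These included Nupr1 (4.57 ± 0.34) and Chac1 (4.05 ± 0.50). Interferon response genes had 6 up and 1 down of 40, and 20 up and 2 down adjusted over the list alone (median 1.39, adjusted p = 1.85e-06; adjusted p = 0.729 with an estimated correlation). Gbp2 rose by 3.33 ± 0.57. Monocyte and macrophage genes had 11 up and 2 down of 36, and 12 up and 4 down adjusted over the list alone (median 0.53, adjusted p = 8.89e-04; adjusted p = 0.191 with an estimated correlation). Clec4d rose by 4.56 ± 0.23 and Clec4e by 3.64 ± 0.37. STAT5 and cytokine feedback targets had 6 up and 0 down of 26, and 9 up and 1 down adjusted over the list alone (median 0.40, adjusted p = 0.00147; adjusted p = 0.192 with an estimated correlation). Cdkn1a rose by 3.58 ± 0.32 and the repressor gene Bcl6 by 2.19 ± 0.32. Cholesterol synthesis genes had 9 of 20 up on either count (median 0.83, adjusted p = 2.75e-04; adjusted p = 0.457 with an estimated correlation). Apoptosis genes had 9 up and 1 down of 22, and 11 up and 2 down adjusted over the list alone (median 0.65, adjusted p = 8.20e-04; adjusted p = 0.368 with an estimated correlation). Bcl2 fell by 1.87 ± 0.20 and Birc3 rose by 2.21 ± 0.22. Myeloid transcription factors had 12 up and 4 down of 44, and 18 up and 6 down adjusted over the list alone (median 0.47, adjusted p = 0.00615; adjusted p = 0.457 with an estimated correlation).

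Ribosome biogenesis and MYC-linked growth genes had 16 down and 2 up of 61, and 24 down and 2 up adjusted over the list alone (median -0.59, adjusted p = 1.92e-08; adjusted p = 0.368 with an estimated correlation). Grwd1 fell by 1.59 ± 0.26, Wdr12 by 1.45 ± 0.25 and the pyrimidine synthesis gene Cad by 1.64 ± 0.26. Cell cycle genes had 8 down and 1 up of 84, and 15 down and 2 up adjusted over the list alone (median -0.40, adjusted p = 1.85e-06; adjusted p = 0.503 with an estimated correlation). Oxidative phosphorylation genes had 3 of 51 down, and 0 adjusted over the list alone (median -0.42, adjusted p = 1.20e-05; adjusted p = 0.614 with an estimated correlation). Megakaryocyte and platelet markers were called upward, with 2 of 16 up and 4 adjusted over the list alone (median 0.42, adjusted p = 0.0354; 0.0916 without the date block and 0.148 without date 2; adjusted p = 0.503 with an estimated correlation). The thrombin receptor gene F2r rose by 2.79 ± 0.52. Primary granule genes (median -0.11, adjusted p = 0.420), secondary and tertiary granule genes (0.21, adjusted p = 0.193), dendritic cell genes (0.09, adjusted p = 0.216), glycolysis genes (-0.32, adjusted p = 0.0561, and 0.0436 without date 2, 0.466 there with an estimated correlation) and immediate early genes (-0.11, adjusted p = 0.272) were not called. Mpo differed by 0.16 ± 0.25, Elane by -0.68 ± 0.32, Ltf by 0.35 ± 0.55, Camp by -0.05 ± 0.49 and Csf1r by 0.45 ± 0.22, with adjusted p of 0.727, 0.210, 0.735, 0.963 and 0.212. Stem and early progenitor genes had a median of -0.07 and a mean of 0.10 (adjusted p = 0.862), and stroma and endothelium markers -0.12 and 0.28 (adjusted p = 0.779).

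Without the date block the count in knockout cells was 293, all among the 1321, and with only the 2 groups fitted 673. Of the 88 named genes 50 stayed past the threshold without the block and 38 did not. Of those given above, Serpinb2, Cad, F2r, Gbp2, Map2k6, Bcl6, Wdr12 and Jun lost their call, at adjusted p of 0.0505 to 0.313. It was 656, 678 and 470 without knockout untreated replicate 1, 2 or 3, and 677 and 612 without knockout treated replicate 2 or 3.

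The responses of both genotypes were correlated across genes. Across the 11815 genes the log2 changes in knockout and control cells correlated with Pearson's r = 0.800 and Spearman's rho = 0.719, though genes are not independent replicates. Within dates r was 0.806, 0.357 and 0.787, and between a control pair of one date and a knockout pair of another 0.389 to 0.660. The 497 genes that rose in control cells had a median log2 change of 1.57 there and 1.55 in knockout cells, and 487 had the same direction in the latter. The 303 that fell had medians of -1.23 and -1.09. Since genes called in control cells were picked on those arrays, they were also chosen without a date and measured on it. On date 1 the 68 genes chosen as rising had medians of 2.68 in control and 2.65 in knockout cells, on date 2 the 688 had 0.99 and 1.53, and on date 3 the 34 had 3.48 and 3.34. Of the rising genes 387 were called in both genotypes, where independent lists would share 33.4, and of the falling ones 202, where independent lists would share 13.5. No array is shared between the 2 treatment comparisons, but both used the same estimate of each gene's spread and the same date block. The 2 lists are therefore not independent, and the numbers for independent lists are no test of the overlap.

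**Figure D4:**
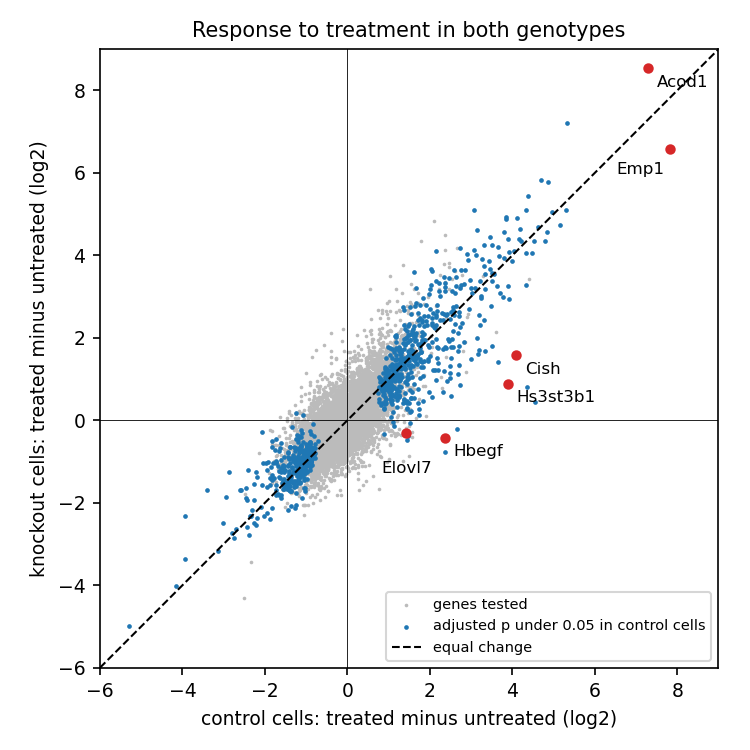
Log2 change with treatment in knockout cells (vertical axis) against control cells (horizontal axis) for each of 11815 genes, with genes past the threshold in control cells in blue, 6 labelled genes in red and the dashed line at equal change. Acod1 (7.30 and 8.54) lies above the line, and Emp1 (7.83 and 6.58), Cish (4.10 and 1.58), Hbegf, Hs3st3b1 and Elovl7 lie below it.

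The test of the difference between the responses called 0 genes in limma. At an unadjusted p under 0.05 there were 291, fewer than a share of 0.05 of the 11815 genes tested. In the simulated data this test recovered 0% of genes changed by 1 on the log2 scale and 55% of those changed by 2. A count of 0 therefore does not show equal responses. The smallest adjusted p was 0.484. Cish had that smallest value, with a response lower in knockout cells by -2.53 ± 0.36 (SE) and by -2.93, -1.92 and -2.73 on the 3 dates. Adjusted over the list of STAT5 and cytokine feedback targets alone its adjusted p was 0.00106. With array weights, an alternative added after seeing the data, Cish was the 1 gene called (adjusted p = 0.0141), and its adjusted p over all alternatives reached from 0.0141 to 1. For Socs2 the probe set that had risen by 5.01 in control cells differed by -4.63 ± 0.51 (-3.93, -5.61 and -4.35 on the 3 dates; adjusted p = 0.0713 over all probe sets) and the other by -3.65 ± 0.47 (adjusted p = 0.152), and the set that stood for the gene by -0.69 ± 0.51. Under the stricter intensity filter the former set stood for Socs2 and was the 1 gene called (adjusted p = 0.0160 among 7702 genes).

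The other genes with the smallest p that were lower in knockout response were Hbegf (-2.78 ± 0.51), Hs3st3b1 (-3.01 ± 0.58), Elovl7 (-1.73 ± 0.34) and Pkib (-1.98 ± 0.39), each at an adjusted p of 0.858. Higher in knockout response were Cx3cr1, the fractalkine receptor gene (2.31 ± 0.47), Pbxip1 (1.30 ± 0.32), Tnfsf9 (1.98 ± 0.51), Ifnlr1 (1.12 ± 0.29) and Slc26a11 (1.89 ± 0.49), of which Cx3cr1 had an adjusted p of 0.858 and the others of 1. Other probe sets of Hs3st3b1 gave 0.03, -0.30 and -0.03, so its value rests on 1 probe set, while 5 further sets of Elovl7 gave -0.55 to -2.36. Adjusted over the list alone, Cx3cr1 passed among monocyte and macrophage genes, Batf3 (-4.09 ± 0.91) among dendritic cell genes and myeloid transcription factors, Vdr (-1.40 ± 0.34) among the latter, and Thy1 (-1.85 ± 0.46) among T and NK markers. Pim1 differed by 0.09 ± 0.34.

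As lists, 5 responded differently in knockout cells, each with 0 members past the threshold over all genes and adjusted over the list alone. Ribosome biogenesis genes had a more negative response (median difference -0.35, adjusted p = 2.16e-08; adjusted p = 0.368 with an estimated correlation; 3.44e-04 without date 2, and 0.464 there with an estimated correlation), with Srm at -1.14 ± 0.45 and Gnl3 at -1.10 ± 0.46. Immediate early and heat shock genes had a more positive one (0.57, adjusted p = 0.0203; adjusted p = 0.590 with an estimated correlation; 0.00605 without date 2, and 0.640 there with an estimated correlation), with Fos at 1.69 ± 0.63 and Nr4a1 at 1.63 ± 0.65. The calls of interferon response genes (0.78, adjusted p = 1.18e-04; adjusted p = 0.765 with an estimated correlation), secondary and tertiary granule genes (0.48, adjusted p = 5.46e-05; adjusted p = 0.503 with an estimated correlation) and oxidative phosphorylation genes (-0.19, adjusted p = 0.0387; 0.127 without the date block; adjusted p = 0.779 with an estimated correlation) went with date 2, whose RNA ratios are given above. Without date 2 their adjusted p was 0.221, 0.403 and 0.582. Rsad2, for example, differed by 0.23, 4.13 and 1.73 on the 3 dates, and Camp by -0.11, 4.01 and -0.06. On date 2 the title of the knockout treated array also carried another tag than that of the knockout untreated array. Signals of the knockout treated array were 5061 against 17860 for Xist and 1802 against 763 for Eif2s3y. RNA ratios, whatever the tag marks and the mix of mice cannot be told apart there. Chemokines (0.32, adjusted p = 0.0892) and STAT5 targets (-0.28, adjusted p = 0.179, and 0.0351 without date 2, 0.466 there with an estimated correlation) were not called. For dendritic cell genes the median was 0.04 and the mean -0.30 (adjusted p = 0.290, and 0.0226 without date 2), and for stroma and endothelium markers the median was 0.15 (adjusted p = 0.368, and 0.0360 without date 2). Without date 2 both had an adjusted p of 0.640 with an estimated correlation.

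Without treatment few genes were called between the genotypes. In the simulated data this comparison recovered 13% of genes changed by 1 on the log2 scale and 83% of those changed by 2, so smaller differences may have been missed. Stat5a was lower in knockout cells by -3.82 ± 0.39 and Stat5b by -4.28 ± 0.47 (SE, n = 3, limma adjusted p = 0.0208 for both). These were the 2 genes called of 11815. At an unadjusted p under 0.05 there were 262, fewer than a share of 0.05 of the genes tested. Cish differed by -0.05 ± 0.26, Socs2 by -0.20 ± 0.36, Pim1 by -0.54 ± 0.24, Mpo by -0.02 ± 0.25, Elane by 0.30 ± 0.32, Ltf by -0.18 ± 0.55, Camp by -0.27 ± 0.49 and Csf1r by 0.06 ± 0.22, each at an adjusted p of 1. Megakaryocyte and platelet markers were lower in knockout cells as a list (16 genes, median -0.52, adjusted p = 4.72e-05; adjusted p = 0.192 with an estimated correlation), with Rab27b at -0.82 ± 0.32, Vwf at -0.64 ± 0.27 and Pf4 at -0.56 ± 0.36. Stroma and endothelium markers (11 genes, median -0.41, adjusted p = 0.00735; adjusted p = 0.457 with an estimated correlation), with the angiopoietin receptor gene Tek at -0.76 ± 0.26, were lower too. So were stem and early progenitor genes (-0.23, adjusted p = 0.00267; adjusted p = 0.539 with an estimated correlation), with Nkx2-3 at -0.99 ± 0.38, and erythroid markers (-0.37, adjusted p = 0.0184; adjusted p = 0.539 with an estimated correlation).

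Ribosome biogenesis genes (median 0.15, adjusted p = 0.00179; adjusted p = 0.544 with an estimated correlation; 0.0592 without date 2), oxidative phosphorylation genes (0.11, adjusted p = 0.00912; adjusted p = 0.767 with an estimated correlation) and cell cycle genes (0.07, adjusted p = 0.0202; adjusted p = 0.739 with an estimated correlation; 0.0710 without the date block) were higher as lists in untreated knockout cells. In none of these 7 lists did a member pass over all genes or adjusted over the list alone. Sex-linked genes (1.29, adjusted p = 0.0851, and 0.0240 without the date block) and chemokines (-0.31, adjusted p = 0.0781, 0.0462 without the date block and 0.0313 without date 2, 0.801 there with an estimated correlation) were not called. Neither targeted gene was called, with a count of 0, without control untreated replicate 1, 2 or 3, without knockout treated replicate 1, or without knockout untreated replicate 1 or 3, and 1 of them was called without control treated replicate 3. The highest adjusted p of Stat5a in such a fit was 0.234. Without the block Stat5a was called (adjusted p = 0.00985) and Stat5b was not (adjusted p = 0.238).

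With treatment 13 genes differed between the genotypes, all lower in knockout cells, with 1149 genes at an unadjusted p under 0.05. They included Stat5b (-4.35 ± 0.47, SE, limma adjusted p = 0.0122) and Stat5a (-3.70 ± 0.39, adjusted p = 0.0122). Cish had the smallest p, though not the largest difference (-2.57 ± 0.26, adjusted p = 0.0122, and -2.58, -2.37 and -2.77 on the 3 dates). The heparan sulfate sulfotransferase gene Hs3st3b1 was lower by -3.37 ± 0.41 (adjusted p = 0.0263), with signals of 916 ± 522 in control and 75.2 ± 49.5 in knockout treated cells, and the growth factor gene Hbegf by -2.79 ± 0.36 (adjusted p = 0.0313), with 773 ± 434 and 97.7 ± 63.2. The others were the receptor genes Ffar2 (-2.19 ± 0.33) and S1pr3 (-2.02 ± 0.27), Pkib (-1.96 ± 0.28), the fatty acid elongase gene Elovl7 (-1.87 ± 0.24) and Muc13 (-1.54 ± 0.22), and Dcaf1 and 2 uncharacterized genes that the naming rule did not take. When all probe sets were tested separately, the 2 Socs2 sets that had risen in control cells had the smallest adjusted p of the comparison, 0.00499, at -4.26 ± 0.36 and -3.74 ± 0.33, and the set that stood for Socs2 had -0.90 ± 0.36 (adjusted p = 0.513 over genes). Other probe sets of Hs3st3b1 gave -0.43, -0.41 and 0.10, another of Hbegf gave -1.89, and those of S1pr3 gave -1.80 and 0.01.

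**Figure D5:**
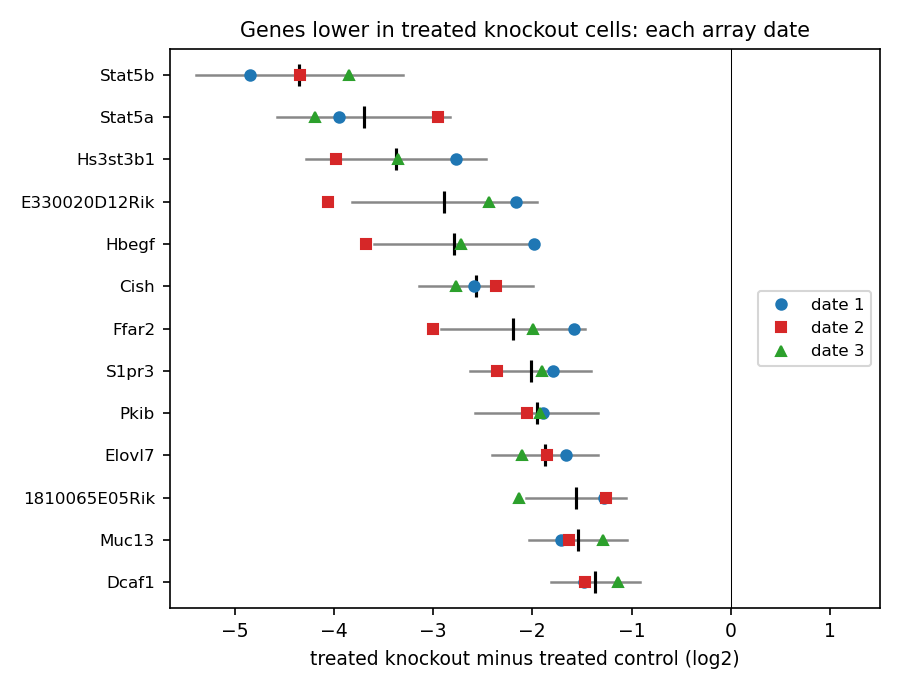
Difference between treated knockout and treated control cells (log2, horizontal axis) for the 13 genes past the threshold, with 1 symbol per array date, a tick at the estimate and a line for its 95% confidence interval. All 3 dates lie below 0 for each gene, with Cish at -2.58, -2.37 and -2.77.

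Of these 13 genes, 12 had a smaller treatment response in knockout cells, 11 had a positive treatment change in control cells and 5 were called as rising there. The comparisons share the treated control arrays, and with no effect at all 50 simulations gave means of 12.9 smaller responses (12 to 13) and 12.4 positive changes (9 to 13). Both simulated means lie near the limit of 13, so these 2 counts could hardly exceed them and decide nothing. For the 5 called as rising, independent lists would give 0.547, but the shared treated control arrays make that no test. Stat5a and Stat5b, the targeted genes, had treatment changes of -0.62 ± 0.39 and -0.50 ± 0.47 in control cells. Genes just short of the threshold were Thy1 (-2.12 ± 0.32, adjusted p = 0.0561), Cx3cr1 (2.03 ± 0.33, adjusted p = 0.0795), Tnfsf9 (2.09 ± 0.36, adjusted p = 0.0898) and the metal transporter gene Slc11a1 (1.64 ± 0.29, adjusted p = 0.104). Batf3 differed by -3.25 ± 0.64 (adjusted p = 0.179), Pim1 by -0.45 ± 0.24 (adjusted p = 0.529), Mpo by -0.30 ± 0.25, Elane by 0.09 ± 0.32, Csf1r by -0.05 ± 0.22, Ltf by 0.73 ± 0.55 and Camp by 1.01 ± 0.49 (0.22, 2.42 and 0.40 on the 3 dates).

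Secondary and tertiary granule genes were higher in treated knockout cells as a list (median 0.39, camera adjusted p = 0.00179; adjusted p = 0.557 with an estimated correlation), with 0 of 34 past the threshold over all genes and 1, Slc11a1, adjusted over the list alone. Without date 2 the median was 0.12 (adjusted p = 0.0240; adjusted p = 0.696 with an estimated correlation). Interferon response genes were higher (0.61, adjusted p = 5.76e-04; adjusted p = 0.767 with an estimated correlation; 0.0697 without date 2) and ribosome biogenesis genes lower (-0.17, adjusted p = 0.00268; adjusted p = 0.551 with an estimated correlation; 0.0423 without date 2, and 0.596 there with an estimated correlation), each with 0 members past the threshold on either count. STAT5 and cytokine feedback targets had 1 of 26 lower, Cish, and 4 lower and 2 higher adjusted over the list alone (median -0.42, adjusted p = 0.0892; 0.0394 without the date block and 0.00361 without date 2). Monocyte and macrophage genes had 0 past the threshold and 6 higher and 6 lower adjusted over the list alone (0.17, adjusted p = 0.582), with the mannose receptor gene Mrc1 at -1.84 ± 0.35, Ccl6 at -1.61 ± 0.31 and Cx3cr1 as above. B lineage markers had a median of 0.77 (adjusted p = 0.0914), with Ighm at 0.87 ± 0.19, the 1 member past the threshold adjusted over the list alone. Lists that were called only without date 2 were cell cycle genes (median 0.15, adjusted p = 1.24e-04) and oxidative phosphorylation genes (0.22, adjusted p = 9.12e-06), both higher, with 0.0906 and 0.784 on all dates. Primary granule genes were higher too (0.12, adjusted p = 0.0347, and 0.850 on all dates). Lower without date 2 were stem and early progenitor genes (-0.24, adjusted p = 0.00765, and 0.684 on all dates), erythroid markers (-0.28, adjusted p = 0.00266, and 0.716) and megakaryocyte and platelet markers (-0.31, adjusted p = 0.00515, and 0.249). With an estimated correlation none of these 6 lists was called without date 2 (adjusted p of 0.464 to 0.801), nor were STAT5 targets (adjusted p = 0.464). For stem genes the median on all dates was 0.05 and the mean -0.01, for erythroid markers 0.03 and -0.01, and for dendritic cell genes 0.05 and -0.22.

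The 13 genes rested on few arrays and on the block. Without the block 1 gene, Stat5a, was called, the other 9 of 10 named genes had adjusted p of 0.0812 (Cish) to 0.999, and with only the 2 groups fitted 0. The count was 0 without knockout treated replicate 1, 2 or 3 or control treated replicate 3, 2 and 3 without control treated replicate 1 or 2, 4, 5 and 4 without control untreated replicate 1, 2 or 3, and 3 and 7 without knockout untreated replicate 1 or 3. In those fits the adjusted p of Cish was at most 0.133, and over all alternatives it reached from 5.16e-04 to 0.614. Without date 2, 9 genes were called, 8 lower and 1 higher, and 3 of them were among the 13. Cish had -2.67 ± 0.20. The higher one was Fos (1.96, adjusted p = 0.0246), and Batf3 was among the lower ones (-3.26, adjusted p = 0.00930).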

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

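The tests of array date 2, and the use of the planned estimated correlation to weigh these calls, were chosen only after the results were seen. In all, 5 gene lists had a treatment response that differed between knockout and control cells by the test of the difference itself, limma's camera with a preset correlation over 130 list tests. None of the 5 was called with an estimated correlation (adjusted p = 0.368 to 0.779). The median difference, knockout minus control on the log2 scale, was 0.48 for secondary and tertiary granule genes, -0.35 for ribosome biogenesis and MYC-linked growth genes, -0.19 for oxidative phosphorylation genes, 0.78 for interferon response genes and 0.57 for immediate early and heat shock genes.

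The arrays of date 2, which differed in RNA ratios, sex signals and 1 title tag of unknown meaning, are a candidate cause for part of this. For ribosome biogenesis and for immediate early and heat shock genes this stays open: these 2 lists were called from dates 1 and 3 alone at the preset correlation, with medians of -0.18 and 0.34 (ratios of 0.513 and 0.606 to those on all dates), but not at an estimated one (adjusted p = 0.464 and 0.640). For the other 3 lists at most a ratio of 0.414 of the median was left without date 2 and none was called, which is consistent with a large part coming from that date. Genes of a list that vary together between arrays remain open for all 5, since the estimated correlation within a list was at least 0.103, above the preset 0.01, and with it no list was called. A difference in response caused by the loss of Stat5a and Stat5b, which the design names, stays open and was not tested apart from these.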

How the results depend on the processing

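Array weights and the list tests without array date 2, at either correlation, were chosen only after the data were seen. Counts of called genes are given for treatment in control cells (main value 800), treatment in knockout cells (1321), the difference of responses (0), and knockout against control without (2) and with treatment (13). Without the date block that pairs the arrays they were 165, 293, 0, 1 and 1, so the block raised most of them, and every gene called for treatment without it was also called with it. With no intensity filter they were 443 and 797 for treatment and 4 for treated cells. With only the 2 groups fitted, on fewer arrays, they were 214, 673, 0 untreated and 0 treated. Without date 1 they were 80, 230, 0 and 0, without date 3 40, 113, 0 and 0, both on fewer arrays and leaving date 2 in. Array weights gave 2595 in control cells, 1 for the difference and 23 for treated cells. The stricter filter gave 1 for the difference (Socs2, through another probe set). A constant of 1 gave 0 untreated and 2 treated, the mean of probe sets 1 untreated, quantile normalization 5 treated and equal medians 8 treated. The correlation of the responses was 0.357 within date 2 against 0.800. Where no reason is given the cause was not tested. Leaving out 1 array gave 237 to 1038, 470 to 1754, 0 to 0, 0 to 2 and 0 to 11.

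For the list test of oxidative phosphorylation genes in treated cells the direction reversed without date 2 (median 0.22, adjusted p = 9.12e-06, against -0.09 and 0.784 on all dates; adjusted p = 0.759 without date 2 with an estimated correlation), and the cause was not tested. Of 15996 pairs of a named gene's value and a setting, 14623 kept direction and side of the threshold. In the same direction, 1013 lost the call and 135 gained it. A further 225 changed direction without a call in either fit, and 0 changed direction with a call in either. Equal medians moved the median of all genes in treated cells from 0.01 to -0.11. Without the block 82 of 178 called values of named genes lost the call. Signal near the background limits dim genes, for which the change is understated.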

Other observations

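The tests of patterns in this part, and the lists of NF-kB pathway and histone genes, were chosen only after the results were seen. These lists hold genes that prompted them or had been named before (Relb, Birc3 and Cd83, and H3f3b and H3c4), so each was also tested without those. In control cells 8 of 23 measured NF-kB pathway genes rose (median 1.40, camera adjusted p = 5.32e-10; adjusted p = 0.184 with an estimated correlation), among them Relb (4.88 ± 0.75), Map3k8 (3.02 ± 0.45), Malt1 (2.37 ± 0.38), Icam1 (2.35 ± 0.59) and Traf1 (2.16 ± 0.56). Members beyond these 8 did not pass. Without the 3 genes named before, 5 of 20 rose (median 0.96, adjusted p = 2.02e-07; adjusted p = 0.265 with an estimated correlation). In knockout cells 14 rose (median 1.91, adjusted p = 1.14e-13; adjusted p = 0.137 with an estimated correlation), including Nfkb2 (3.80 ± 0.86), Nfkbie (2.87 ± 0.51), Traf1 (4.11 ± 0.56) and Tnfaip3 (3.18 ± 0.63). Without the 3 genes it was 11 (median 1.81, adjusted p = 8.89e-11; adjusted p = 0.186 with an estimated correlation). Without date 2, 15 of the 23 rose in control and 18 in knockout cells. The response of the list was larger in knockout cells by a median of 0.66 (adjusted p = 7.09e-05; adjusted p = 0.401 with an estimated correlation), but by 0.11 without date 2 (adjusted p = 0.0953). The untreated genotypes differed by a median of -0.03 (adjusted p = 0.728). With treatment the list was higher in knockout cells by 0.64 (adjusted p = 1.69e-04; adjusted p = 0.401 with an estimated correlation), and by 0.25 without date 2 (adjusted p = 0.0101; adjusted p = 0.507 with an estimated correlation).

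Of 17 measured histone genes 6 fell in control cells (median -0.94, adjusted p = 4.78e-05; adjusted p = 0.110 with an estimated correlation), H3f3b by -3.94 ± 0.55, H3c4 by -3.01 ± 0.30, H3c11 by -2.31 ± 0.50, H3c7 by -1.72 ± 0.34, H2aw by -1.30 ± 0.33 and H2ac19 by -1.25 ± 0.30. In knockout cells 5 fell (median -0.70, adjusted p = 1.16e-04; adjusted p = 0.110 with an estimated correlation). Without date 2 these counts were 7 and 4. Without H3f3b and H3c4, 4 of 15 fell in control cells (median -0.93, adjusted p = 0.00174) and 3 in knockout cells (median -0.49, adjusted p = 0.00187), both at an adjusted p of 0.186 with an estimated correlation.

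Arrays of date 2 stood apart from the rest, by ratios of 3' to 5' signal and by the first principal component. A change of RNA levels as the whole cause, such as another makeup of cells, would show alike on 2 probe sets of a gene. Over 5484 genes the date 2 difference correlated between 2 probe sets of a gene with r = 0.167 (95% interval 0.134 to 0.196), while the treatment difference of dates 1 and 3 correlated with r = 0.742, which argues against that explanation. Probe-specific loss of signal from RNA or labelling of lower quality is consistent with the low value of 0.167. Part of the difference may still be one of RNA levels.

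For the 13 genes lower in treated knockout cells, a weaker response in general is argued against by the held-out dates, where the ratio of the knockout to the control median rise was 0.990, 1.54 and 0.958, each above 0.384 for Cish (mean 1.16 ± 0.328, SD over 3 dates, above 1 only through date 2). The arrays of date 2 are argued against for Stat5a, Stat5b and Cish, all 3 of which were called without them (adjusted p = 0.00930), while 0 of the other 10 were called, at adjusted p of 0.0775 to 0.245 on fewer arrays (3 residual degrees of freedom against 6). As measured, values argue against date 2 as the source of most of the difference in those 10. Each was lower on dates 1 and 3 too, and its difference without date 2 had a ratio of 0.797 to 1.10 to that on all dates. Their median was -1.86 without it and -1.99 with it (median SE 0.254 and 0.276). All 10 kept more than they lost even less 2 SE. This criterion was set after the test of calls had left the matter open and with the estimates already seen. The genes were picked on all 3 dates, and a gene that differed mainly on date 2 would have had a wide spread. Such a gene was unlikely to be called, so these values describe the 10 genes as measured and are no independent test. The size of the difference in genes picked without date 2 stays open. A different share of male and female mice is argued against for part of the genes by date 1, where all arrays had the signal of males. Of the 18 genes best separated on dates 2 and 3 beside the targeted pair, 17 had the same direction there (53.9% of all genes did), though genes are not independent. Only 8 of the 18 were among the 11 called genes beside that pair, so the remaining called genes were not covered. A dependence of Cish on STAT5 may remain as a hypothesis. Cish was named in advance as a STAT5 target, but its difference of responses did not pass over all genes (limma adjusted p = 0.484). Socs2 was named in advance as well. Its lowest adjusted p for that difference was 0.0713 over all probe sets tested separately, and 0.0160 under the stricter filter (limma). The probe set that stood for Socs2 in the main fit did not pass, and the other was singled out after its values were seen. The tests of other causes were chosen on the same data.

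Xist, expressed from the inactive X of female cells, and the Y-linked Eif2s3y varied by date. On date 1 all arrays had Xist signals of 64.3 to 172 and Eif2s3y signals of 2169 to 2324. On date 2 the control arrays had Xist at 34538 and 23523 with Eif2s3y at 2.98 and 2.97, and the knockout arrays had 17860 and 5061 with 763 and 1802. On date 3 Xist was 7088 to 9188, with Eif2s3y at 777 and 783 on control and 1833 and 1601 on knockout arrays.

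Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. For treatment in control cells the real split gave 800 genes and the highest other 0, and 1 split, the real one, reached that value. For treatment in knockout cells these numbers were 1321, 0 and 1, for the difference of responses 0, 1 and 10, for untreated genotypes 2, 1 and 1, and for treated genotypes 13, 1 and 1. Among the 4 splits that part all 3 dates, the highest other was 0 in each comparison. In the other splits a real change of a gene adds to its spread, which lowers their counts. The low counts are therefore no support for the real splits.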
